A study of Mus musculus with 6 samples.

How the data were processed

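The study measured transcript levels in C3H10T1/2 cells on 6 two-colour arrays, 3 from cultures given DMSO and 3 from cultures given 1 µM dexamethasone for 90 minutes. Per the labels' protocols, RNA was isolated with a column kit and turned into amino-allyl cDNA; the sample was coupled to Cy3 and a common pool to Cy5. The labels describe the pool as RNA of cells given DMSO, dexamethasone or myostatin, while the series description names vehicle and treated cells without myostatin. The groups and replicate numbers came from the sample titles.

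The deposited values were taken as log2 ratios of the 2 channels, judged from the values themselves: they are signed, have 3 decimals and often equal the log2 of a ratio of small whole numbers. On 4 arrays some of the deposited values exceed 100 in size, which no ratio of scanner intensities gives, so those columns are not log2 ratios throughout. Per the submitters' processing notes limma was used, with no version or step. Background correction, normalization and spot filters are not given in the sources used here, and scanner intensities were not used here. The scale is therefore inferred, the columns are not centred (their medians ran from -0.12 to 0.57), and the direction was only found likely. Of 38467 probes, 31071 had values on all arrays.

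Genes were named through the platform annotation supplied with the table. It listed 30216 of the probes: 29456 with 1 symbol and 760 with several. The other 8251 were unlisted and kept as unnamed probes. The Entrez identifiers of 28735 single-symbol probes were found in a RefSeq gene table, which changed 0 symbols. No genome build was named for the array, so no positions are given. Probes with 1 symbol were averaged per gene (avereps), 6325 genes having more than 1 probe; the others stayed as they were. A gene or unnamed probe needed values on at least 2 arrays of each group.

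The comparison was fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) on the deposited log2 ratios without further normalization and without a block, two-sided, with Benjamini-Hochberg adjustment at 0.05. The pool cancels in the difference between groups only if all arrays used the same pool, which was not verified. Fold values are 2 to the power of the difference. With 3 against 3 arrays an exact permutation test of a single gene cannot go below 0.1, so none was used. SE is the moderated standard error of the difference, and SD the spread of the 3 arrays of a group.

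There were 19 gene lists, written before the data were examined from general knowledge of glucocorticoid action, mesenchymal cells and other cell types. Each was tested with camera (cameraPR at a preset correlation of 0.01 on the moderated statistics), again with an estimated correlation on the genes measured on all arrays, and by counting members past 0.05 adjusted over all genes and adjusted over the list alone. The camera p were adjusted over the lists. The run with an estimated correlation used camera on the values, with degrees of freedom from the 6 arrays rather than the number of genes. A larger p there is therefore not due to the correlation alone. The rule for naming genes, also written before, took the 12 largest non-overlapping differences per direction among those passing, or, as happened here since none passed, the 10 smallest p; to these it added the 6 orientation targets and up to 4 members per list with the smallest p. The report states where a gene outside this rule was named.

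The direction was checked in 2 ways. A pool with a share w of dexamethasone RNA predicts the mean of the 2 groups' log ratios from their difference; w was fitted on a grid from 0.05 to 0.95 for both readings and the residual sums of squares were compared. The best share was 0.38 for sample over pool. The other check was the sign of the orientation targets.

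The fit was tested on simulated data with genes changed by known sizes. Its noise was normal and independent between arrays, with 1 spread per gene, pooled over the real arrays of both groups. In the planned fit on 27046 genes and unnamed probes, limma recovered 0%, 12%, 28% and 40% of 50 genes each changed by 1, 2, 3 and 4 on the log2 scale, with 1 false call. After the low-signal filter, on 17152, it recovered 14%, 28%, 56% and 68%, with 2 false calls. The unequal spread of the groups and the 2 sets of arrays described in the results were not simulated. Recovery and false calls on the real arrays may therefore differ. The estimated prior degrees of freedom were 1.09 in the planned fit and 1.23 after the filter.

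Other settings fixed before the data were examined were a replicate block, median centring and quantile normalization between arrays, other handling of missing values, each probe on its own, array weights, a robust prior, a trend on the mean log ratio, a minimum of 1.5-fold, and leaving out each array. After seeing the data, further settings were added: leaving out low-signal probes, leaving out values beyond 10 in size, a block for 2 sets of arrays seen in the correlations, and leaving out the 2994 probes whose identifiers start with mC, among which were many for housekeeping genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.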

Results

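C3H10T1/2, a mouse mesenchymal cell line that can be turned into fat, muscle, bone or cartilage cells, was given 1 µM dexamethasone or its solvent DMSO (the vehicle) for 90 minutes. Dexamethasone is a synthetic glucocorticoid that activates the glucocorticoid receptor, a transcription factor. RNA from 3 vehicle and 3 dexamethasone cultures, biological replicates per the series description, was hybridised on 6 two-colour arrays, with the sample in Cy3 and a common pool of RNA in Cy5. The design implies a single comparison: which transcripts differed between dexamethasone and vehicle at this early time. The values, taken as log2 ratios, cover 38467 probes, of which 29456 carried exactly 1 gene symbol. Averaging the probes of a gene and requiring 2 values per group left 27046 genes or unnamed probes, 18793 of them with a symbol.

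The number of arrays limits the precision, and the arrays were of unequal quality. Missing values numbered 552, 825 and 932 on the vehicle arrays and 1695, 2837 and 4290 on the dexamethasone arrays (replicates 1, 2 and 3 in turn). The medians were -0.10, -0.12 and 0.16 for vehicle and -0.12, 0.57 and 0.41 for dexamethasone, so the deposited columns were not centred on 0. Values equal to ratios of whole numbers from 1 to 10, as spots of very few intensity units give, made up 1.86%, 1.95% and 7.73% of the vehicle values and 3.79%, 10.5% and 12.7% of the dexamethasone values. At 3 decimals a value can also match by coincidence, and the share expected so was not computed. A log2 ratio of exactly 1 occurred 0, 10 and 200 times on the vehicle arrays and 70, 334 and 393 times on the dexamethasone arrays. The matches on vehicle 1 and vehicle 2 therefore need not be low signal. Which way the ratio was taken is not stated in the labels. Sample over pool is likely but not settled, and with the sign turned every "higher" and "lower" in the text, before and after, would change places. Across all genes and unnamed probes the median dexamethasone minus vehicle difference was 0.32, and it was -0.09 after each array was centred on its median. Without probes that had a missing value, such a whole-number ratio or a value beyond 10 in size on any array, it was 0.17. With all probes, it was 0.147 without dexamethasone replicate 2 and 0.570 without dexamethasone replicate 1. In vehicle 1, vehicle 2 and dexamethasone 1 alone it was -0.05, and in the other 3 arrays 0.25, so the shift was absent in 1 set of arrays.

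**Figure D1:**
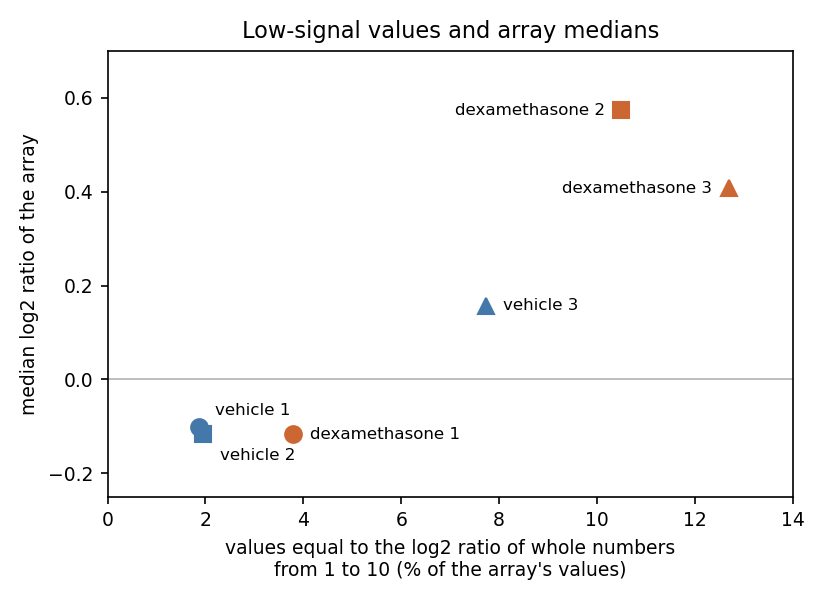
Each point is 1 array, blue for vehicle and orange for dexamethasone. The x axis gives the percentage of the array's values that equal the log2 ratio of whole numbers from 1 to 10, and the y axis the array's median log2 ratio; vehicle 1, vehicle 2 and dexamethasone 1 sit at the lower left, and vehicle 3, dexamethasone 2 and dexamethasone 3 have medians of 0.16, 0.57 and 0.41.

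The clearest separations between dexamethasone and vehicle, ranked by p, were at genes that include known glucocorticoid targets. Dusp1, a phosphatase that inactivates MAP kinases, had a log2 ratio of -2.79 ± 0.11 (SD, n = 3) in vehicle and 1.46 ± 0.12 (SD, n = 3) in dexamethasone, a 19.1-fold higher level with dexamethasone. Glul, which encodes glutamine synthetase, was 10.9-fold higher (-2.11 ± 0.10 against 1.34 ± 0.08, SD, n = 3 each), and Cebpb, a transcription factor of early fat cell differentiation, was 9.09-fold higher (-1.63 ± 0.18 against 1.55 ± 0.31, SD, n = 3 each). Rgs4, a regulator of G protein signalling, was 4.45-fold lower with dexamethasone (0.44 ± 0.06 against -1.72 ± 0.15, SD, n = 3 each). For these 4 genes all 3 dexamethasone values lay beyond all 3 vehicle values.

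None of the differences passed the planned test. limma called 0 of the 27046 genes and unnamed probes at a Benjamini-Hochberg adjusted p under 0.05, 0 higher and 0 lower. At an unadjusted p under 0.05 there were 1468, of which 1199 were higher and 269 lower with dexamethasone, against 1352 that chance alone would give. The count was 786 and 695 without vehicle replicate 1 or 2, and 6947 without dexamethasone replicate 1, so its place relative to chance depends on single arrays. Without dexamethasone replicate 1, both dexamethasone arrays left belong to the same set as vehicle 3, so treatment and array set are partly confounded. This holds for every result without dexamethasone replicate 1. The higher share of the 1468 was 81.7%, and it was 72.9% of 896 after median centring and 62.4% of 988 after quantile normalization. Without 1 array it ran from 72.0% of 1132 (without dexamethasone replicate 2) to 93.9% of 1630 (without vehicle replicate 3). With the sign turned, 269 would be higher and 1199 lower, and these higher shares would be 18.3%, 27.1%, 37.6%, 28.0% and 6.07%. The 10 smallest p belonged to Dusp1, Glul, Tcim, Rgs2, Adm, Nfil3, Cebpb, Spsb1, Rgs4 and the unnamed probe mMC004778. Their limma adjusted p ran from 0.0556 for Dusp1 to 0.141 for Rgs4, so none of them passed. Tcim differed by 2.83 ± 0.16 (SE) on the log2 scale, Rgs2 by 2.71 ± 0.18, Adm, which encodes the vasodilator peptide adrenomedullin, by 2.47 ± 0.17, Nfil3 by 2.39 ± 0.18 and Spsb1 by 2.41 ± 0.20. The probe mMC004778 differed by 2.48 ± 0.20 (SE).

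A filter chosen after seeing the data changed this outcome. It left out each probe that had, on any array, a missing value, a ratio of whole numbers from 1 to 10, or a value beyond 10 in size, which removed 15355 probes. Since a value can match such a ratio by coincidence, a probe left out was not always of low signal. On the remaining 17152 genes and unnamed probes limma called 29 at an adjusted p under 0.05, with 26 higher and 3 lower. The 3 lower genes were Rgs4, Ccl7 and Ccl2, and among the higher ones were Dusp1, Glul, Tcim, Adm, Rgs2, Cebpb, Spsb1, Fabp4, Fkbp5 and Per1. At an unadjusted p under 0.05 there were 1279, against 858 by chance. This count fell below 858 without any 1 of the vehicle arrays (654, 530 and 725 without vehicle replicate 1, 2 and 3) and was 5650 without dexamethasone replicate 1, so an excess over chance is not shown. Among the 17152, 1779 had all 3 dexamethasone values above and 1600 all 3 below the vehicle values, together 19.7%. Chance gives 10% for exchangeable arrays only; with the unequal spread and the 2 sets of arrays described below, the share is not shown to lie above chance. The count of 29 depended on the fit: it was 4 after median centring (3 higher, 1 lower) and 0 after quantile normalization. It was 0 with the array sets or the replicate numbers as a block and 1 with array weights. Without 1 array it ran from 0 to 934: 934 without dexamethasone replicate 1, 5 without dexamethasone replicate 2 and 0 without any other array. Treatment and array set are partly confounded in the fit that gave 934.

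**Figure D2:**
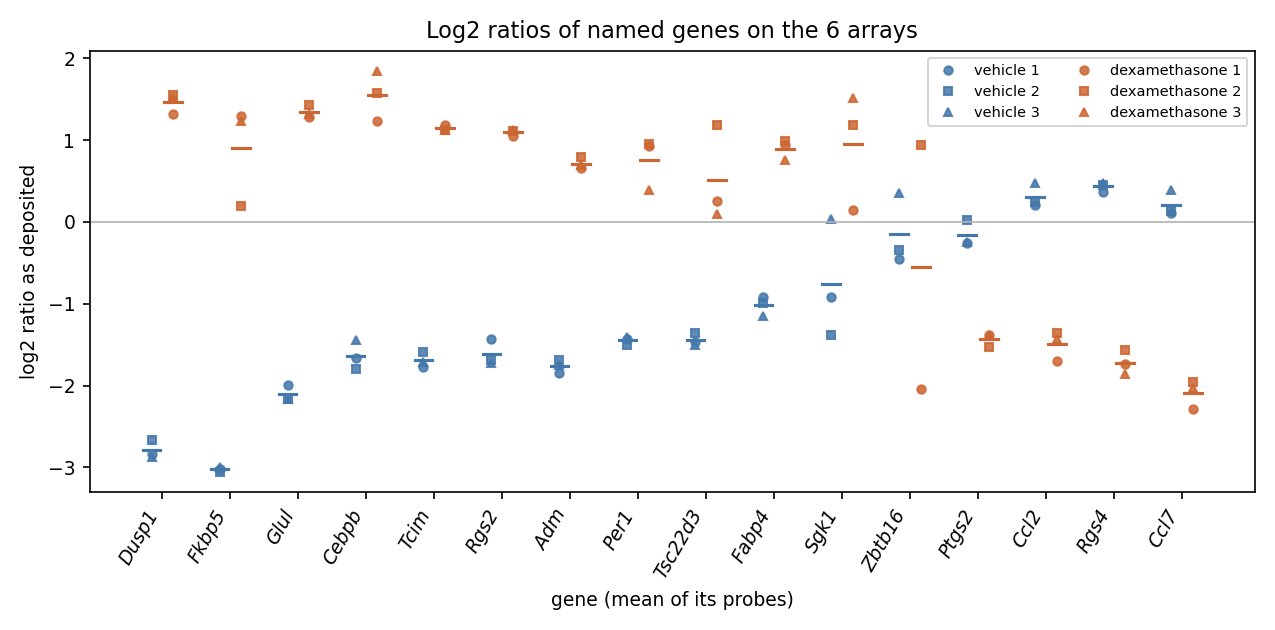
Each marker is 1 array's log2 ratio as deposited for a gene, averaged over the gene's probes; blue is vehicle, orange is dexamethasone, the marker shape gives the replicate, and bars are group means. For Dusp1 the vehicle mean is -2.79 and the dexamethasone mean 1.46, for Ccl7 they are 0.21 and -2.09, and Zbtb16 has 2 dexamethasone values that lie on either side of the vehicle values.

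The direction of the ratios, sample over pool, is called likely and not settled, since the labels give the dyes but not which way the ratio was taken. A pool that mixes RNA of both treatments sets how the mean of the 2 groups' log ratios depends on their difference. Over the 29 genes and probes called after the filter, a mixture read as sample over pool left a residual sum of squares 0.198 times that of the opposite reading. Because the planned fit called none, these 29 took the place of its calls. Over the 95 at an unadjusted p under 0.001 in the planned fit the quotient was 1.43, which favours the opposite reading. The other check was the sign of 6 textbook glucocorticoid targets, of which 5 were higher as deposited. With the sign turned, the counts would read 3 higher and 26 lower after the filter. The lowest correlation between 2 arrays was a Spearman coefficient of -0.33 across all probes, between vehicle 2 and dexamethasone 3. A pool of both treatments allows that under either reading, so it does not decide the direction. Over the 101 at an unadjusted p under 0.001 after the filter the quotient was 0.909. The direction was called likely because the mixture over the 29 and the orientation targets pointed the same way.

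Of the 6 orientation targets, 5 were higher with dexamethasone at p under 0.05 adjusted over the list alone, and 0 passed over all genes. Fkbp5, a co-chaperone of the glucocorticoid receptor, stood at -3.02 ± 0.03 in vehicle and 0.91 ± 0.62 in dexamethasone (SD, n = 3 each), 15.3-fold higher. The clock gene Per1 was 4.62-fold higher, Tsc22d3 (the anti-inflammatory protein GILZ) 3.88-fold and the kinase Sgk1 3.26-fold. The 4 probes of Tsc22d3 disagreed, with differences of 4.49, 2.36, 0.92 and 0.05. Zbtb16 did not pass (-0.15 ± 0.44 against -0.55 ± 2.11, SD, n = 3 and 2, SE of the difference 1.01). Since the sign of these genes was 1 of the 2 checks behind the direction, their being higher is no independent evidence of a rise. The list's median difference of 2.08 was 1.76 above that of all genes, with a camera adjusted p of 1.3e-07 at a preset correlation and an adjusted p of 0.0287 with an estimated correlation.

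Among 25 other genes known to be bound or induced by the glucocorticoid receptor, 16 were higher and 1 was lower at p under 0.05 adjusted over the list alone, 0 passed over all genes, and 8 did not pass either way. Ranked by p, Glul came first, followed by Rgs2 (6.53-fold), Fam107a (6.14-fold; -1.69 ± 0.19 against 0.93 ± 0.27, SD, n = 3 each) and the transcription factor Klf9 (3.80-fold; -1.36 ± 0.11 against 0.56 ± 0.09, SD, n = 3 each). Lcn2 (31.9-fold; -2.62 ± 0.75 against 2.37 ± 1.64, SD, n = 3 each) passed over the list with a larger difference than Glul, and Mt2 (8.48-fold) with one larger than Rgs2; both were named after their values were seen. Klf9, Fam107a, Nfil3 and Zbtb16 have 1 probe each, which the low-signal filter left out. Cebpd, a partner of Cebpb, was 4.45-fold higher, and Ddit4, an inhibitor of mTOR signalling, 2.86-fold. Angptl4, a secreted inhibitor of lipoprotein lipase and a known receptor target, was the lower member, 2.16-fold below vehicle (0.30 ± 0.07 against -0.81 ± 0.35, SD, n = 3 each). The list's median was 1.52, against 0.32 for all genes, with a camera adjusted p of 4.0e-12, and an adjusted p of 0.0287 with an estimated correlation. The count of 17 was 8 after quantile normalization.

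Of 22 inflammatory genes measured, 13 had a difference below 0 and 9 above; 4 were lower at p under 0.05 adjusted over the list alone, 0 were higher and 0 passed over all genes. The chemokine genes Ccl7 (0.21 ± 0.16 against -2.09 ± 0.18) and Ccl2 (0.30 ± 0.15 against -1.50 ± 0.18; SD, n = 3 each) were 4.93-fold and 3.48-fold lower with dexamethasone. Ptgs2, which encodes cyclooxygenase-2, was 2.41-fold lower and the chemokine gene Cxcl5 2.57-fold lower. The list's median difference was -0.43, which is -0.75 relative to all genes, with a camera adjusted p of 9.6e-07 at the preset correlation. The list did not pass in the run with an estimated correlation, with a camera adjusted p of 0.0742. The estimate was 0.029, and that run also had fewer degrees of freedom. The count of 4 was 2 with the quantile normalization and 10 without dexamethasone replicate 1.

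**Figure D3:**
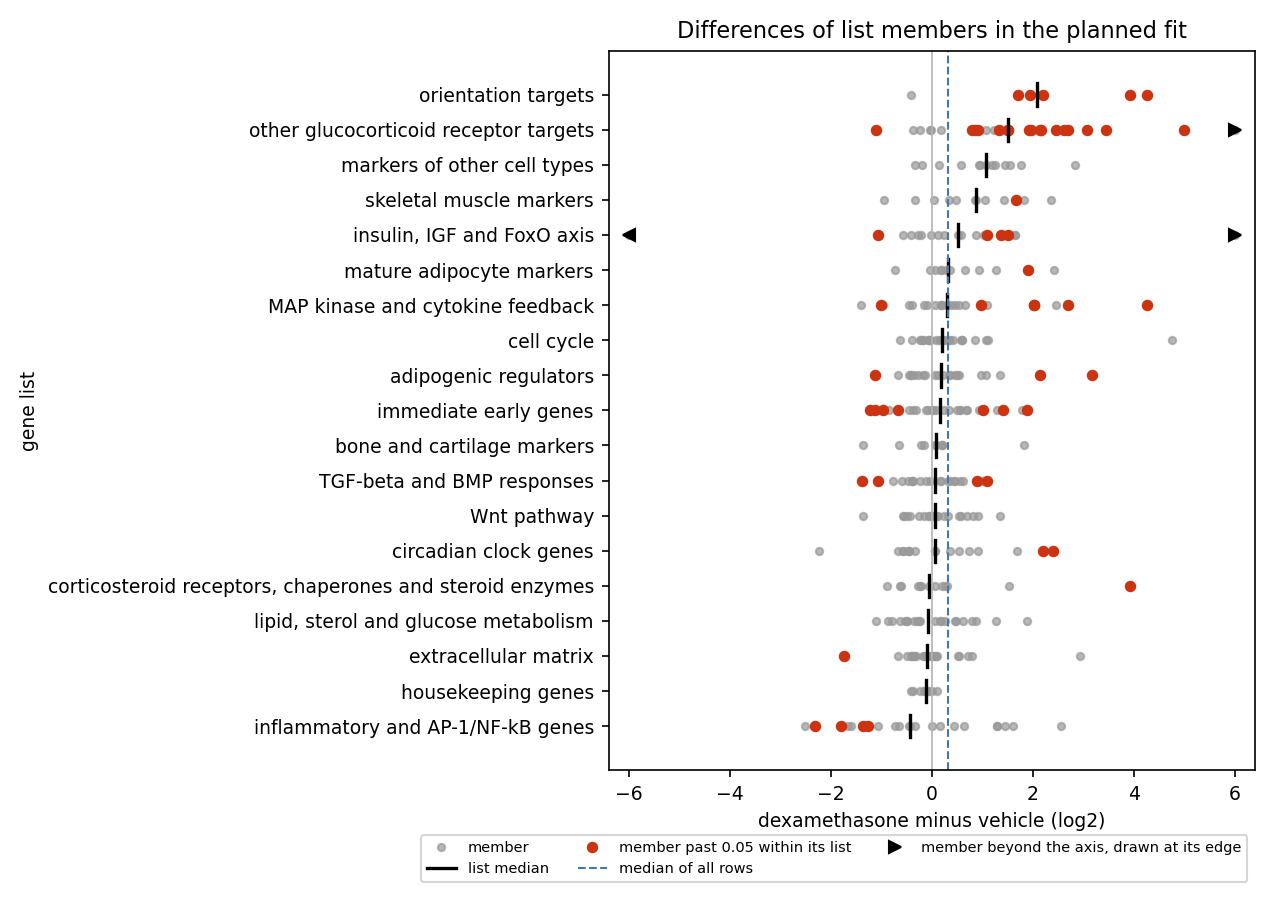
Each dot is a list member's log2 difference, dexamethasone minus vehicle; red dots passed 0.05 adjusted over the list alone, black bars are list medians, and the dashed line is the median of all genes, 0.32. The 3 members beyond 6 in size, Sult1a1 (39.2), Akt2 (-12.8) and Igfbp6 (6.39), are drawn as triangles at the edge. Such sizes need not be changes in expression, since some deposited values are too large for log2 ratios. The orientation targets have a median of 2.08 and the inflammatory genes one of -0.43.

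Immediate early genes, which cells switch on within minutes of a stimulus, went both ways. Of 26 measured, 3 were higher and 4 lower at p under 0.05 adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.453). The growth-associated genes Ccn1 (2.67-fold) and Ccn2 (2.02-fold) and the nuclear receptor gene Nr4a1 (3.70-fold) were higher. The transcription factor genes Klf10 (2.34-fold), Egr2 (2.18-fold) and Klf4 (-0.66 ± 0.17, SE, on the log2 scale) were lower, as was Egr1 (1.95-fold), which falls outside the naming rule and was named after its value was seen. The count of 7 ran from 0 to 11 over the alternatives, with 0 after median centring, after quantile normalization and without any 1 of the vehicle arrays, and 11 without dexamethasone replicate 1.

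Of 23 genes of MAP kinase and cytokine feedback, 5 were higher and 1 lower at p under 0.05 adjusted over the list alone. Beside Dusp1 and Rgs2, the small GTPase genes Gem (4.08-fold) and Rasd1 (4.10-fold) were higher. Socs2 (1.97-fold higher) and Dusp10 (2.00-fold lower) complete the 6 and were named after their values were seen. The list did not pass as a whole (camera adjusted p = 0.176), and the count of 6 was 3 after median centring. In the insulin, IGF and FoxO axis, 3 of 19 were higher and 1 was lower: Ddit4, Pik3r1 (2.14-fold), which encodes the regulatory subunit of PI3 kinase, and the transcription factor gene Foxo3 (2.57-fold) were higher, and the ubiquitin ligase gene Fbxo32 was 2.09-fold lower. That list had a camera adjusted p of 0.359, and its count was 0 after either normalization between arrays, 0 without any 1 of the vehicle arrays and 1 without dexamethasone replicate 3.

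Among TGF-beta and BMP response genes, 2 of 22 were higher and 2 lower at p under 0.05 adjusted over the list alone. The transcriptional repressor gene Tgif1 was 2.59-fold lower (0.02 ± 0.02 against -1.36 ± 0.12, SD, n = 3 each) and the BMP antagonist gene Grem1 2.08-fold lower. The BMP-responsive genes Id1 (2.13-fold) and Id4 (1.86-fold) were higher. The list had a camera adjusted p of 0.13, and the count of 4 was 0 after either normalization between arrays, 0 without any 1 of the vehicle arrays and 7 without dexamethasone replicate 2. The list passed after median centring (median -0.35, adjusted p = 0.0401), without vehicle replicate 3 (0.0417) and without dexamethasone replicate 1 (0.0349). None of the 22 Wnt pathway genes passed (camera adjusted p = 0.212); Dkk2, a secreted Wnt inhibitor, had the smallest p, with a difference of -0.57 ± 0.21 (SE).

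Genes of cell identity gave few passing members. Of 22 adipogenic regulators, Cebpb and Cebpd were higher and Egr2 lower at p under 0.05 adjusted over the list alone (camera adjusted p = 0.571), and the count of 3 was 1 after either normalization and without any 1 of vehicle replicates 1 to 3 or dexamethasone replicate 3. Of 12 mature adipocyte markers, the fatty acid binding protein gene Fabp4 was higher (3.77-fold; -1.02 ± 0.12 against 0.89 ± 0.12, SD, n = 3 each), and the list did not pass (camera adjusted p = 0.440). Its count of 1 was 0 after either normalization, 2 without vehicle replicate 3 and 5 without dexamethasone replicate 1. Of 12 skeletal muscle markers, Myog, a transcription factor of muscle differentiation, was 3.17-fold higher (camera adjusted p = 0.13 for the list; 0 members after either normalization, 4 without dexamethasone replicate 1). None of the 10 bone and cartilage markers passed (camera adjusted p = 0.219); the cartilage transcription factor gene Sox9 had a difference of -1.36 ± 0.32 (SE) in the planned fit, and 1 member passed after the low-signal filter and 1 without dexamethasone replicate 1.

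Markers of blood, endothelial and epithelial cells, which this line is not thought to express, had a median difference of 1.08, while 0 of 13 passed (camera adjusted p = 0.272) and 2 passed without dexamethasone replicate 1. Only 6 of these 13, and 8 of the 12 muscle markers (median 0.87), had a probe free of low signal. Over these members the medians after the low-signal filter were 1.22 and 0.68. The positive medians were therefore not confined to low-signal probes. In vehicle 1, vehicle 2 and dexamethasone 1 alone, the medians were -0.09 for the markers of other cell types and -0.15 for the muscle markers, and in vehicle 3, dexamethasone 2 and dexamethasone 3 they were 1.39 and 1.04. The median of 1.08 was 0.346 without dexamethasone replicate 2 and 2.01 without dexamethasone replicate 1, and the muscle median was 0.262 without dexamethasone replicate 3. After median centring the camera adjusted p of the markers of other cell types was 0.0456.

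Of 17 circadian clock genes, Per1 and Nfil3 (5.26-fold), a repressor of clock output genes, were higher at p under 0.05 adjusted over the list alone. The list did not pass (camera adjusted p = 0.809), and the count of 2 was 1 after median centring, 0 after quantile normalization and 9 without dexamethasone replicate 1. Of 13 corticosteroid receptors, chaperones and steroid enzymes, Fkbp5 alone passed; Nr3c1, the glucocorticoid receptor gene itself, had a difference of -0.89 ± 0.32 (SE) and did not. That list had a camera adjusted p of 0.272, and 4 members passed without dexamethasone replicate 1 and 0 after quantile normalization. None of 26 cell cycle genes passed (camera adjusted p = 0.551); the cell cycle inhibitor gene Cdkn1a, at 0.86 ± 0.22 (SE), had the smallest p there.

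Another 3 lists lay below the median of all genes with little movement of their members. Of 25 extracellular matrix genes, Has2, a hyaluronan synthase gene, was 3.32-fold lower (-0.11 ± 0.21 against -1.84 ± 0.21, SD, n = 3 each) and the rest did not pass; after either normalization, and without vehicle replicate 2 or vehicle replicate 3, 0 passed. None of 22 lipid, sterol and glucose metabolism genes passed; the cholesterol synthesis genes Cyp51 and Sqle had differences of -0.78 ± 0.19 and -0.86 ± 0.25 (SE), and 5 members passed after the low-signal filter, 3 without dexamethasone replicate 1 and 2 without dexamethasone replicate 3. None of 10 housekeeping genes passed, and Sdha had a difference of -0.37 ± 0.20 (SE). The medians were -0.09, -0.08 and -0.12, and the camera adjusted p 0.0136, 0.0184 and 0.0136 for the matrix, metabolism and housekeeping lists. These calls were lost in the camera run with an estimated correlation (adjusted p = 0.494, 0.498 and 0.494), which also had fewer degrees of freedom. After the low-signal filter they were lost too (camera adjusted p of 0.0784, 0.0659 and 0.0659). They were also lost without dexamethasone replicate 3 (0.0607, 0.0607 and 0.209), the matrix list without dexamethasone replicate 2 (0.865), and the other pair of lists without vehicle replicate 2 (0.0706 each). In 6 of the 19 lists the median was above 0 while the camera statistic was below that of all genes. The test is relative to all genes, whose median difference was 0.32, or 0.17 after the low-signal filter.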

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

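The low-signal filter and its combinations, the array-set block, and the removal of mC probes or of values beyond 10 were chosen after the data were seen. The planned count of 0 genes became 2 (2 higher) with the trend, 5 (5 higher) on genes measured on all 6 arrays, 2 (2 higher) without a filter on missing values, 2 (2 higher) without mC probes and 29 (26 higher, 3 lower) without low-signal probes; it stayed at 0 with the replicate block, both normalizations, array weights, the robust prior, single probes, the array-set block, without values beyond 10, with the 1.5-fold minimum and without any 1 array. Fewer genes were tested without mC probes, without low-signal probes and with values on all 6 arrays. The trend fit tested the same 27046, and the fit without a filter on missing values tested more, 28329. The shared variance was estimated anew in each of these fits. Otherwise the cause was not tested. The count of 29 (26 higher, 3 lower) after the low-signal filter was 0 (0 and 0) with the replicate block, 0 (0 and 0) with quantile normalization, 0 (0 and 0) with the array-set block, 1 (1 and 0) with array weights, 4 (3 and 1) with median centring, 19 (17 and 2) with the robust prior and 49 (44 and 5) with the trend. Without 1 array it ran from 0 to 934 (0 to 815 higher, 0 to 119 lower), the top being without dexamethasone replicate 1, where treatment and array set are partly confounded. All 29 kept their direction in each of these fits. The adjusted p of the 10 genes with the smallest p ran from 0.00744 to 0.989 over their alternatives, all with the planned direction. In all of these genes the dexamethasone values lay beyond the vehicle values. Leaving out an array, a block, array weights or another variance estimate therefore could not turn the direction.

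Same-numbered arrays deviated from their group means with Spearman coefficients of 0.28, -0.17 and 0.35 across genes. Dexamethasone 1 went best with vehicle 2 (0.33), dexamethasone 2 with vehicle 3 (0.28) and dexamethasone 3 with vehicle 3 (0.35). Only pairs within a set of arrays had positive coefficients. These values thus follow the sets, and pairing by replicate number is neither shown nor excluded. The replicate block gave 0 calls in the planned fit and 0 after the filter.

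Of 19 lists, 6 passed in the planned fit; 3 passed with the array-set block, 3 without low-signal probes and 2 with an estimated correlation, and from 3 to 7 without 1 array (3 without dexamethasone replicate 3). The orientation targets, other receptor targets and inflammatory genes passed in all 18 refits with the preset correlation. Counts of members past 0.05 adjusted over the list alone ran from 8 to 18 for the other receptor targets (17 planned), 2 to 10 for inflammatory genes (4), 0 to 11 for immediate early genes (7), 0 to 9 for clock genes (2), 1 to 6 for adipogenic regulators (3), 0 to 5 for adipocyte markers (1), 0 to 4 for muscle markers (1), 0 to 1 for bone and cartilage markers (0), 0 to 2 for markers of other cell types (0), 0 to 7 for TGF-beta and BMP responses (4), 0 to 1 for extracellular matrix (1), 3 to 9 for MAP kinase feedback (6), 0 to 6 for the insulin axis (4), 0 to 5 for lipid, sterol and glucose metabolism (0) and 0 to 4 for corticosteroid receptors and chaperones (1). The median of the extracellular matrix list turned positive without dexamethasone replicate 2 (0.0179; range -0.192 to 0.0179 without 1 array), and that of the lipid, sterol and glucose list with array weights (0.0597), without vehicle replicate 3 (0.0649), without dexamethasone replicate 1 (0.042) and without a filter on missing values (0.0693; range -0.17 to 0.0649 without 1 array).

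The 79 named genes were picked mainly by small p, and in most of them the groups did not overlap. Leaving out an array, a block, array weights or another variance estimate could not turn the direction of those genes. The count of kept directions was thus largely fixed in advance and is little evidence of stability. Of 1409 alternative values of the 79 named genes, 1404 had the planned direction and 24 passed the threshold. The 5 that turned were of genes that did not pass in their lists: Zbtb16 with array weights (0.15), Tnnt1 with median centring (-0.0755), Col10a1 with median centring (-0.21) and quantile normalization (-0.60), and Fzd4 with quantile normalization (-0.21). The mixture check of direction gave 0.198 for changes of at least 2-fold, 0.193 after centring, 0.909 over those at an unadjusted p under 0.001 after the filter, and 1.43, the opposite reading, over those in the planned fit. Signal over background could not be judged, since no intensities were used.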

Other observations

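Some genes outside the fixed lists were among the 29 that passed after the low-signal filter; they were singled out after their values were seen, and none passed the planned test. Nrip1, a corepressor of nuclear receptors, was 3.35-fold higher with dexamethasone (-0.95 ± 0.04 against 0.79 ± 0.14, SD, n = 3 each), and Vdr, the vitamin D receptor gene, 3.15-fold higher (-1.06 ± 0.06 against 0.59 ± 0.16). Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis, was 6.22-fold higher, the secreted factor gene Ism1 5.26-fold, and Tob2, of the antiproliferative Tob family, 3.14-fold. The galactosyltransferase gene B4galt1 (3.53-fold), the vesicle transport gene Rab3d (4.47-fold), the AMP deaminase gene Ampd3 (3.64-fold) and Jade2 (3.93-fold) were also higher. In all 29 the 3 dexamethasone values lay beyond the 3 vehicle values. The difference therefore had to have the same sign in vehicle 1, vehicle 2 and dexamethasone 1 as in the other 3 arrays. That sign is no evidence against an effect of the array sets.

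Of the tests below, those of exchanged arrays, of the pool, of the low-signal variance and of a shift shared by a set were chosen after their results were at least partly seen. For the last, the threshold of 2.5 was also written after its value. The test of noise by 2 probes of a gene was added late, with its bounds written before its value, in place of the ratio of SDs and a correlation between arrays, which do not decide. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. In the planned fit all 10 called at least the real 0, and the highest other called 2158. After the low-signal filter 2 of the 10 called at least the real 29, the highest other being 567, and for unadjusted p under 0.05 in the planned fit 2 of the 10 reached the real 1468, the highest other being 7875. In all 3 cases the split with the larger count set vehicle 1, vehicle 2 and dexamethasone 1 against vehicle 3, dexamethasone 2 and dexamethasone 3, which points to a structure of the samples.

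That structure is the first pattern: between a vehicle and a dexamethasone array, the Spearman coefficient across all probes ran from 0.34 to 0.52 within a set and from -0.33 to -0.00024 between sets. The value nearest 0 was that of vehicle 3 and dexamethasone 1, which had 0.125 among probes free of low signal. The structure is not confined to low-signal probes, since the gap between same-set and other-set Spearman coefficients was 0.533 among probes free of low signal and 0.477 among the others. An exchange of vehicle 3 with dexamethasone 1 is argued against by the orientation targets other than Zbtb16, of which 5 of 5 were higher on dexamethasone 1. A pool with another share of dexamethasone RNA on 1 set cannot be told apart from no such shift: over the receptor target lists vehicle 3 differed from the mean of vehicle 1 and 2 by a median of 0.0605, against 0.064 over all genes, with members on both sides, from -0.59 to 1.576 (a first version over the 26 genes called higher gave -0.02 but used genes chosen partly for agreement among vehicle arrays). A shared processing day or the authors' normalization stays open and untested, and with the set as a block 0 genes passed, with or without the low-signal filter.

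The second pattern is that 0 genes passed the planned test although known targets differed several-fold. A candidate explanation is that the spread of low-signal genes entered the variance estimate shared by all genes, and that the number of tests fell: the same fit called 29 once low-signal probes were left out. The test was chosen after the values were seen and does not measure the share of each part. The number of tests was not the only change. In each of the 29 the difference was the same in both fits while the unadjusted limma p fell. For Dusp1 this p fell from 2.1e-06 to 4.6e-07 and the SE from 0.179 to 0.142. The filter's count itself ran from 0 to 934 when 1 array was left out. No biological explanation was tested for this pattern.

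The third pattern is that the dexamethasone arrays scattered more than the vehicle arrays, through dexamethasone 2 and 3: median SDs between 2 arrays were 0.355 to 0.474 in pairs with either, 0.117 to 0.150 between dexamethasone 1 and vehicle arrays, and 0.0955 to 0.103 among vehicle arrays. Outside the receptor target lists the median SD was 0.504 in dexamethasone and 0.117 in vehicle, a ratio of 4.32 (2.31 over 10 housekeeping genes, 0.216 against 0.093). The housekeeping ratio is not like for like, since Actb, Tbp, Sdha and Hprt are each means of 23 or more probes. A shift shared by the arrays of a set is not the whole cause on these arrays, since the median SD between dexamethasone 2 and 3, of 1 set, was 3.81 times that between vehicle 1 and 2, of the other (95% bootstrap interval 3.72 to 3.93). That ratio sets 1 pair of arrays against 1 other pair. Its interval, like the intervals that follow, does not cover variation between arrays or cultures. Noise that differs from spot to spot fits the difference between dexamethasone 2 and 3: between 2 probes of a gene, both free of low signal, it had a Spearman coefficient of 0.054 (95% bootstrap interval 0.022 to 0.087, 3916 genes), against 0.326 for vehicle 1 minus vehicle 2. Cultures responding to different degrees would raise the ratio at receptor targets beyond that elsewhere; it was 4.01 there (95% bootstrap interval 1.80 to 6.85, 25 genes), so this could be neither seen nor excluded, and with 2 of 3 dexamethasone but 1 of 3 vehicle arrays in the set with more low-signal values, treatment and array quality are partly confounded.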
